A study of Mus musculus with 6 samples.

How the data were processed

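Total RNA of mammary tumors from 6 samples, 3 given vehicle and 3 given the drug combination, was isolated with a column kit, labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The values analysed are the authors' deposited table of log2 expression per probe set, for 22690 probe sets. The submitters' processing notes name Affymetrix Expression Console. Its version, the summarisation algorithm and the normalization are not given in the sources used here. The log base was read from the range of the deposited values, 1.88 to 14.14 over the arrays, and the array medians (6.70 to 6.73) and quartiles were close to equal, so the values were used without further normalization. A normalization that equalises arrays can hide a change shared by most genes. Detection calls were not used here, so no value is given as a bound, and values near 4 or below may lie close to background.

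Probe sets were named through the platform annotation of 2016. Of the probe sets, 20380 had 1 gene symbol, 691 several and 1555 none, and 64 were controls. Of the single-symbol probe sets, 99.9% had an Entrez identifier in the GRCm38.p6 gene table, through which 0 symbols changed. Only probe sets with 1 symbol were tested, and for the 4956 genes with more than 1 of them the probe set with the highest mean over the 6 arrays was used, which left 12393 genes. A symbol in the text stands for that probe set. No coordinates are given, since no genome build is stated for the values. Of the 2310 probe sets that were controls or had no or several symbols, 0 passed limma's adjusted p of 0.05 and 186 had an unadjusted p under 0.05.

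Drug-treated tumors were compared with vehicle by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, Benjamini-Hochberg over all genes, threshold 0.05), with no filter on level and no covariate. An exact permutation test of 3 against 3 cannot give a two-sided p under 0.1 and so cannot pass 0.05. For 45 gene lists with at least 5 measured members, camera was run with a preset inter-gene correlation of 0.01 and adjusted over the lists, and each list's genes were also adjusted over the list alone. The lists covered tumor, stromal, immune and neighbouring cell types, pathways of the 3 drugs and RNA handling. The groups, tests, lists, alternatives and the naming rule were fixed before the data were examined. The rule names, among named genes past the threshold with non-overlapping groups, the 12 with the largest change per direction. Where fewer pass, genes with the smallest unadjusted p fill the 12 and are given as values. It leaves out predicted and unnamed transcripts, olfactory and similar families, and immunoglobulin and T cell receptor segments, and adds each drug target gene and up to 4 members per list with the smallest unadjusted p.

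The procedure was tested on simulated data with 200 of 12393 genes changed, in 20 runs with the real spread and independent noise between genes. It called 55.9% of genes changed by 0.5, 90.1% of those changed by 1 and 97.7% of those changed by 2 on the log2 scale, and 4.7% of its calls were unchanged genes. A list of 54 genes shifted by -0.5 was called in 100% of runs. The changed genes were drawn at random, and the median SE over all real genes was 0.078. The shares therefore do not hold for genes with a larger spread, such as Cd74 with an SE of 0.29. The list shift was also larger than the median changes of -0.16 for mitosis and -0.13 for DNA replication genes. Shifts of that size were not simulated. Genes of a list correlate in real tumors. There the preset correlation of camera makes p-values too small where the true correlation is higher, as with the estimates of 0.71 for mitosis and 0.942 for skeletal muscle genes. The estimates were -0.001 for red blood cell and 0.013 for basal mammary genes, close to the preset value. In those lists a higher correlation does not account for the larger p-values of the run with an estimated correlation, and the cause was not tested. Alternatives were the mean of all probe sets of a gene, a level filter, quantile or median normalization, eBayes with trend and robust settings, array weights, each array left out in turn, other thresholds, an estimated correlation, fry and ranks. After the data were seen, alternatives without the muscle-rich arrays (vehicle replicate 3 and drug replicate 1), with a muscle or adipocyte score as covariate, and without muscle genes in the background were added. Figures were drawn with matplotlib 3.10.9.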

Results

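Gene expression was measured in mammary tumors of mice given vehicle or a drug combination for 21 days. The combination held VX680, an inhibitor of Aurora kinases, miltefosine, an alkylphosphocholine, and WP1066, an inhibitor of JAK2 and STAT3. Each group had 3 samples, and each sample was hybridised to 1 Affymetrix mouse array. The number of arrays limits the precision of every value. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Array medians lay between 6.70 and 6.73 on the log2 scale. Pearson correlations across probe sets, which are not independent replicates, were 0.991 to 0.996 within groups and 0.988 to 0.995 between groups.

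The comparison asked which transcripts differed between tumors of drug-treated and vehicle-treated mice. Drug-treated tumors had lower mean levels of genes for MHC class II antigen presentation, and higher mean levels of squamous differentiation and basal mammary genes. Cd74, the invariant chain of MHC class II, had a mean of 9.21 ± 0.22 (SD, n = 3) in vehicle and 7.25 ± 0.60 (SD, n = 3) in drug-treated tumors, a 3.88-fold lower mean. Sprr1b, a precursor of the cornified envelope, had means of 5.66 ± 0.71 and 7.12 ± 0.36 (SD, n = 3 each), a 2.75-fold higher mean. No single gene passed the threshold over all genes tested. With limma, 0 of 12393 genes reached an adjusted p under 0.05, and the smallest adjusted p was 0.231, shared by 18 genes. At an unadjusted p under 0.05 there were 1275 genes, 666 higher and 609 lower, where 620 would be expected with no change. All drug arrays lay above all vehicle arrays for 958 genes and below them for 1161, together 17.1% of genes against 10% by chance.

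Among the named genes, ranked by unadjusted p because none passed, those with higher means in drug-treated tumors included Sostdc1, a secreted antagonist of BMP signalling, with a log2 difference of 0.88 ± 0.11 (SE, n = 3 per group). Slc2a9, a urate transporter, differed by 0.95 ± 0.14, Klf4, a transcription factor of epithelial differentiation, by 0.63 ± 0.09, and Ccn2, a matricellular growth factor, by 0.57 ± 0.08. Bcl2l15, Sorcs2, Gnmt, Anpep, Capn5 and Akr1b8 had log2 differences of 0.66, 0.59, 0.56, 0.44, 0.42 and 0.36. A second probe set of Capn5 had the opposite sign. Hpd and Ccdc191 differed by 0.34 each, at vehicle means of 3.55 and 3.57 in the low part of the scale. Lower means were found for Tenm4, a teneurin, at -0.80 ± 0.09, Fcrls at -1.08 ± 0.15, Fgl2 at -0.88 ± 0.13 and Psmb8, an immunoproteasome subunit, at -0.74 ± 0.10 (SE, n = 3 per group). Ms4a4c, Cx3cl1, Lpxn, Slain1, Tcf7l1 and Arl2bp had log2 differences of -0.73, -0.59, -0.54, -0.53, -0.52 and -0.33. In each of these genes the 3 drug values lay on one side of the 3 vehicle values. Without drug replicate 2, 3 genes passed with limma, namely Slc2a9, Gsta3 and Serpinb2, of which Serpinb2 was named after its values were seen.

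Genes of antigen presentation fell as a list in the drug-treated tumors. Of 17 measured members 16 had lower means, and 13 had all drug arrays below all vehicle arrays. H2-Aa and H2-Ab1, the chains of the class II molecule I-A, had log2 differences of -2.04 ± 0.35 and -1.94 ± 0.30, and Cd74 of -1.96 ± 0.29 (SE, n = 3 per group). H2-DMa, which helps load class II peptides, differed by -0.74 ± 0.13. The class I genes B2m and H2-K1 had smaller differences, -0.21 ± 0.05 and -0.19 ± 0.05, and these as well as H2-DMa were named after their values were seen. By limma, 12 members passed when adjusted over the list alone and 0 over all genes. The list's median was -0.24 with a camera adjusted p = 1.5e-11 at a preset correlation, and adjusted p = 0.275 with an estimated correlation. B and plasma cell genes also fell as a list, with 16 of 21 members lower, a median of -0.11 and a camera adjusted p = 0.00221, or adjusted p = 0.511 with an estimated correlation. Jchain, the joining chain of polymeric immunoglobulins, differed by -1.84 ± 0.33 and Igha, the IgA heavy chain, by -1.93 ± 0.45, and 3 members passed limma when adjusted over the list alone. The B and plasma cell call ended without vehicle replicate 3, the array richest in skeletal muscle transcripts, where the median was -0.03, and under the filter on low levels. Its median was -0.05 with both muscle-rich arrays left out, -0.20 without vehicle replicate 1, -0.22 without drug replicate 2 and -0.07 with a skeletal muscle score as covariate.

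**Figure D1:**
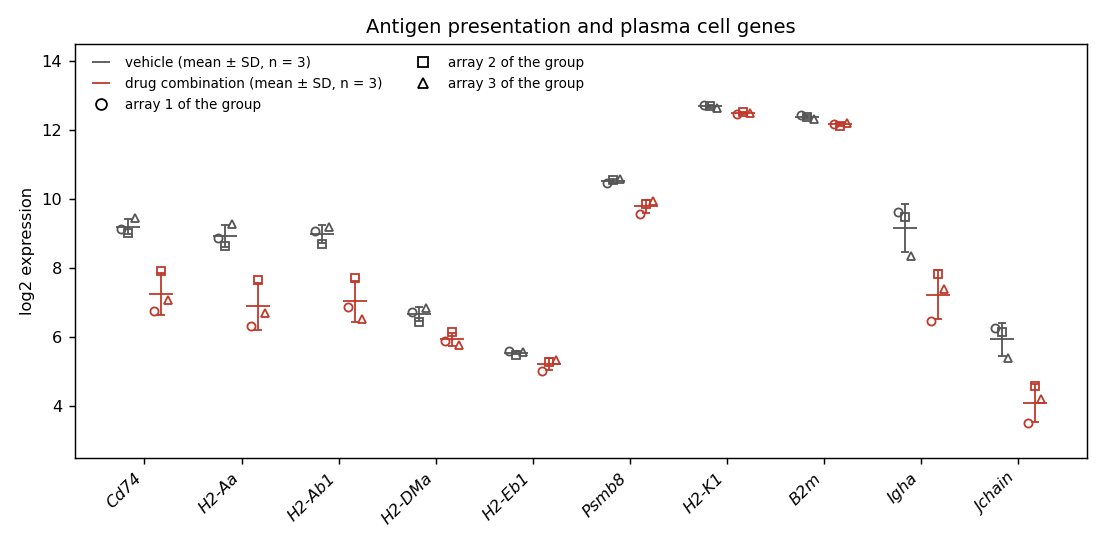
Log2 expression of antigen presentation and plasma cell genes, with 1 point per array, the group mean as a horizontal line and the SD as a bar (n = 3 per group). The drug-treated means of Cd74 and Igha were 7.25 and 7.24 against 9.21 and 9.16 in vehicle, and genes beyond the naming rule were chosen after their values were seen.

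Interferon-stimulated genes fell as a list, with 36 of 37 members lower and a median of -0.45 (camera adjusted p = 1.1e-10 at a preset correlation, adjusted p = 0.515 with an estimated correlation). Cxcl10, a chemokine that attracts T cells, had a log2 difference of -1.14 ± 0.28, Irgm2 and Ifi47, immunity-related GTPases, of -0.73 ± 0.21 and -0.63 ± 0.15, and Trim30a of -0.60 ± 0.18 (SE, n = 3 per group). By limma, 0 members passed when adjusted over the list alone. The drug-treated arrays differed from one another, with list medians of -0.52, -0.42 and 0.25 relative to the mean of the 6 arrays, against 0.34, 0.32 and 0.02 in vehicle. The list's median change was -0.71 without drug replicate 3 and -0.29 without drug replicate 1. Neither the T and NK cell list (adjusted p = 0.0703), nor the chemokine list (adjusted p = 0.081), nor the macrophage list (adjusted p = 0.107) passed with camera. The T and NK cell and chemokine lists passed, as lower, with quantile normalization, with the adipocyte score as covariate and without vehicle replicate 2, the former also without drug replicate 2 and the latter without drug replicate 1. The macrophage list passed, as lower, without vehicle replicate 2 and without drug replicate 1. Within the T and NK cell list, Ccl5, a T cell chemokine, and Cd3d, a chain of the T cell receptor complex, had differences of -0.58 ± 0.10 and -0.52 ± 0.09, and were the 2 members that passed when adjusted over the list alone.

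Genes of mitosis and DNA replication fell as lists by small amounts. All 57 measured mitosis genes had lower means in the drug-treated tumors, with a median of -0.16, and 27 had all drug arrays below all vehicle arrays. Top2a, a topoisomerase of dividing cells, differed by -0.26 ± 0.06, Bub1, a spindle checkpoint kinase, by -0.33 ± 0.09, and the kinesins Kif20a and Kif2c by -0.23 ± 0.06 and -0.33 ± 0.09 (SE, n = 3 per group). Of 54 DNA replication genes 51 had lower means, with a median of -0.13, among them Mcm10 at -0.31 ± 0.06 and Mcm3 at -0.27 ± 0.08. The camera adjusted p was 4.2e-14 for mitosis and 1.5e-11 for DNA replication at a preset correlation, and adjusted p = 0.515 for each with an estimated correlation. By limma, 0 members of either list passed when adjusted over the list alone. Drug replicate 3 had the lowest list medians, and without it the median change of the mitosis genes was -0.09. Of the genes encoding the drugs' targets, Aurka and Aurkb differed by -0.32 ± 0.14 and -0.22 ± 0.12, with all drug arrays below all vehicle arrays. Aurkc, Stat3, Jak2, Akt1 and Akt2 differed by -0.21 ± 0.16, 0.13 ± 0.08, -0.08 ± 0.09, -0.00 ± 0.06 and -0.09 ± 0.06, with overlapping groups. By limma, 0 of the 7 target genes passed over all genes or adjusted over the list alone, and the list did not pass (camera adjusted p = 0.197), though it did, as lower, with the mean of all probe sets of a gene.

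Epithelial genes of the basal and squamous kinds rose as lists. Of 28 squamous differentiation genes 23 had higher means, and 7 passed limma when adjusted over the list alone. Krt6a, a keratin of activated keratinocytes, differed by 1.07 ± 0.27, Sprr1b by 1.46 ± 0.37, Lgals7 by 0.42 ± 0.09 and Sfn by 0.33 ± 0.09 (SE, n = 3 per group). Of 23 basal and myoepithelial genes 16 had higher means, and 6 passed when adjusted over the list alone. Krt14 and Krt17, basal keratins, differed by 0.60 ± 0.11 and 0.92 ± 0.18, Snai2 by 0.31 ± 0.06 and Trp63, a regulator of basal epithelium, by 0.90 ± 0.19, though 1 of 3 probe sets of Trp63 had the opposite sign. Milk protein and secretory genes also rose as a list, with 18 of 23 higher. Olah, a thioesterase that makes medium-chain fatty acids, differed by 1.25 ± 0.29, Lao1 by 1.11 ± 0.31 and Folr1 by 0.53 ± 0.11, and 2 members passed when adjusted over the list alone. The medians and camera adjusted p at a preset correlation were 0.15 and 3.3e-06 for squamous, 0.13 and 0.00149 for basal, and 0.21 and 0.000712 for secretory genes. With an estimated correlation these became adjusted p = 0.275, adjusted p = 0.275 and adjusted p = 0.511. The basal median was 0.25 without vehicle replicate 3 and 0.07 without drug replicate 3, and the secretory median was 0.13 without vehicle replicate 1. The luminal list did not pass (camera adjusted p = 0.675), while Foxa1, a luminal transcription factor, differed by -1.20 ± 0.22 and was its 1 member past limma's threshold when adjusted over the list alone.

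**Figure D2:**
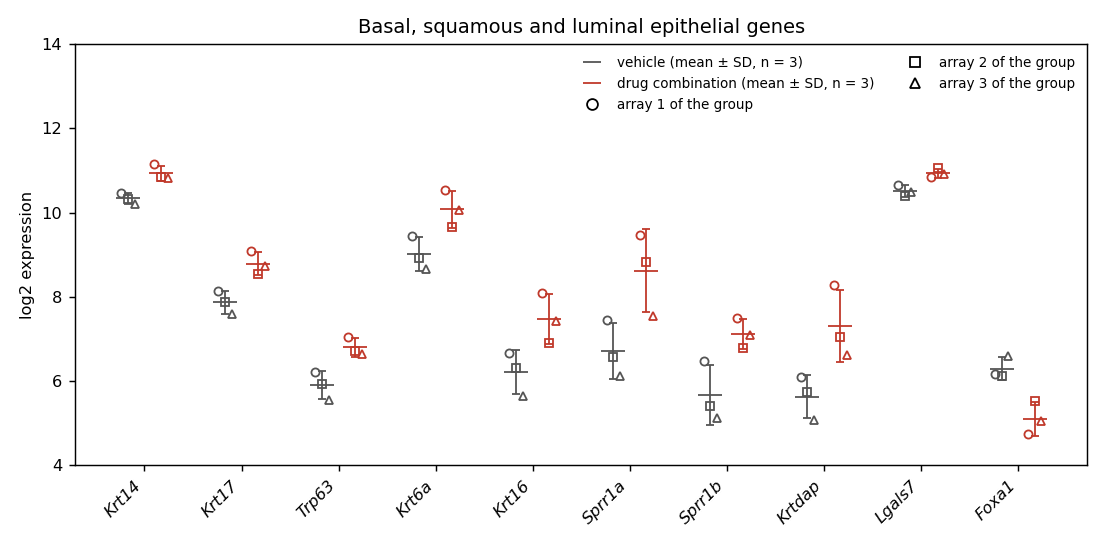
Log2 expression of basal, squamous and luminal epithelial genes, with 1 point per array, the group mean as a horizontal line and the SD as a bar (n = 3 per group). Krt6a had means of 9.01 in vehicle and 10.08 in drug-treated tumors and Foxa1 of 6.30 and 5.10, and genes beyond the naming rule were chosen after their values were seen.

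Detoxification, lipid and red blood cell genes rose as lists. Of 21 NRF2 target genes 19 had higher means, with Gsta3 and Gstm1, glutathione transferases, at 1.02 ± 0.26 and 0.36 ± 0.07, and Nqo1, a quinone reductase, at 0.13 ± 0.05 (SE, n = 3 per group). Of 25 fatty acid and triglyceride synthesis genes 17 had higher means, with Acss2, which makes acetyl-CoA, at 0.37 ± 0.09 and Me1, malic enzyme, at 0.37 ± 0.12. Of 17 red blood cell genes 15 had higher means, with Alas2, the erythroid enzyme of heme synthesis, at 1.63 ± 0.42 and Hbb-b2, a beta globin, at 0.55 ± 0.15. The medians and camera adjusted p at a preset correlation were 0.12 and 0.000396 for NRF2 targets, 0.09 and 0.0129 for lipid synthesis, and 0.11 and 0.000405 for red blood cells. With an estimated correlation these became adjusted p = 0.275, adjusted p = 0.511 and adjusted p = 0.275, and 0 members of these lists passed limma when adjusted over the list alone. The lipid synthesis call ended without vehicle replicate 2 (median 0.01) and without drug replicate 2 (median 0.03). With both muscle-rich arrays left out, the medians were 0.06 for NRF2 targets and 0.15 for lipid synthesis.

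Skeletal muscle genes had lower means in all 32 measured members, with a median of -1.36, but their levels varied as much within as between groups. The list medians relative to the mean of the 6 arrays were 0.40, -0.63 and 2.49 in vehicle and 1.45, -1.66 and -1.74 in drug-treated tumors. Myl1, a fast muscle myosin light chain, differed by -2.89 ± 1.70 and Myh7, a slow muscle myosin, by -1.60 ± 0.85 (SE, n = 3 per group). By limma, 0 members passed when adjusted over the list alone. Camera gave an adjusted p = 3.3e-05 at a preset correlation and adjusted p = 0.707 with an estimated correlation. The call ended without vehicle replicate 3, where the median was -0.52, and the median was -2.39 without drug replicate 1 and -0.86 without drug replicate 3. Skeletal muscle genes also made up 30 of the 50 genes with the largest loadings on the first principal component, which held 42.7% of the variance.

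Fibroblast, mast cell, neutrophil, protease, transition regulator and hypoxia genes rose as lists, with calls that ended when certain single arrays were left out. Of 50 fibroblast and matrix genes 38 had higher means, with a median of 0.16, and 0 passed limma when adjusted over the list alone. Without vehicle replicate 2 the fibroblast median was -0.06 and the call ended, as it did without drug replicate 3 (0.10) and with the adipocyte score as covariate (0.10), and the median was 0.36 without vehicle replicate 3. It was 0.37 with both muscle-rich arrays left out and 0.29 with the skeletal muscle score as covariate. Mast cell and eosinophil genes included Tpsab1, a mast cell tryptase, at 1.67 ± 0.40, and the chymases Cma1 and Mcpt4 at 1.16 ± 0.32 and 0.61 ± 0.14 (SE, n = 3 per group). Of 15 mast cell and eosinophil genes 8 had higher means and 5 passed when adjusted over the list alone. The neutrophil list held Clec4d at 0.63 ± 0.11, the protease list Adam8 at 0.35 ± 0.06, the epithelial-mesenchymal transition list Twist1 at 0.30 ± 0.08, and the hypoxia list Slc2a1, a glucose transporter, at 0.21 ± 0.07. The camera adjusted p at a preset correlation was 0.017 for fibroblasts, 0.0477 for mast cells, 0.0352 for both neutrophils and proteases, 0.0425 for transition regulators and 0.0327 for hypoxia. With an estimated correlation these became adjusted p = 0.852 for fibroblasts, 0.515 for mast cells and for proteases, 0.511 for neutrophils, 0.512 for transition regulators and 0.711 for hypoxia.

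Each of these last 5 lists lost its call in 3 of the 6 settings that left out 1 array. With every array kept, transition regulators also lost their call under the level filter, quantile normalization, the median shift, eBayes with trend and ranks, and mast cells under the level filter, quantile normalization, the median shift, array weights and ranks. Neutrophils lost theirs under quantile normalization, the median shift and ranks, proteases under the median shift, and hypoxia under the median shift and array weights. The mast cell median was 0.06, and it was -0.00 without vehicle replicate 1, 0.04 without drug replicate 1 and 0.06 without drug replicate 3. With its call kept, it was 0.10 with both muscle-rich arrays left out and 0.02 with the skeletal muscle score as covariate. The neutrophil median was 0.16, and it was 0.10 without vehicle replicate 2, 0.07 without drug replicate 1, 0.12 without drug replicate 3 and 0.09, still past the threshold, without vehicle replicate 1. The protease median was 0.12, and it was 0.11 without vehicle replicate 1, 0.05 without vehicle replicate 2 and 0.09 without drug replicate 3. The transition regulator median was 0.12, and it was 0.06 without vehicle replicate 1, 0.03 without vehicle replicate 2 and 0.08 without drug replicate 3. The hypoxia median was 0.09, and it was 0.04 without vehicle replicate 1, 0.06 without vehicle replicate 3 and 0.07 without drug replicate 3, while it was 0.17 and past the threshold without vehicle replicate 2. With the skeletal muscle score as covariate the hypoxia median was 0.03 and its call ended, as it did with both muscle-rich arrays left out (0.09).

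**Figure D3:**
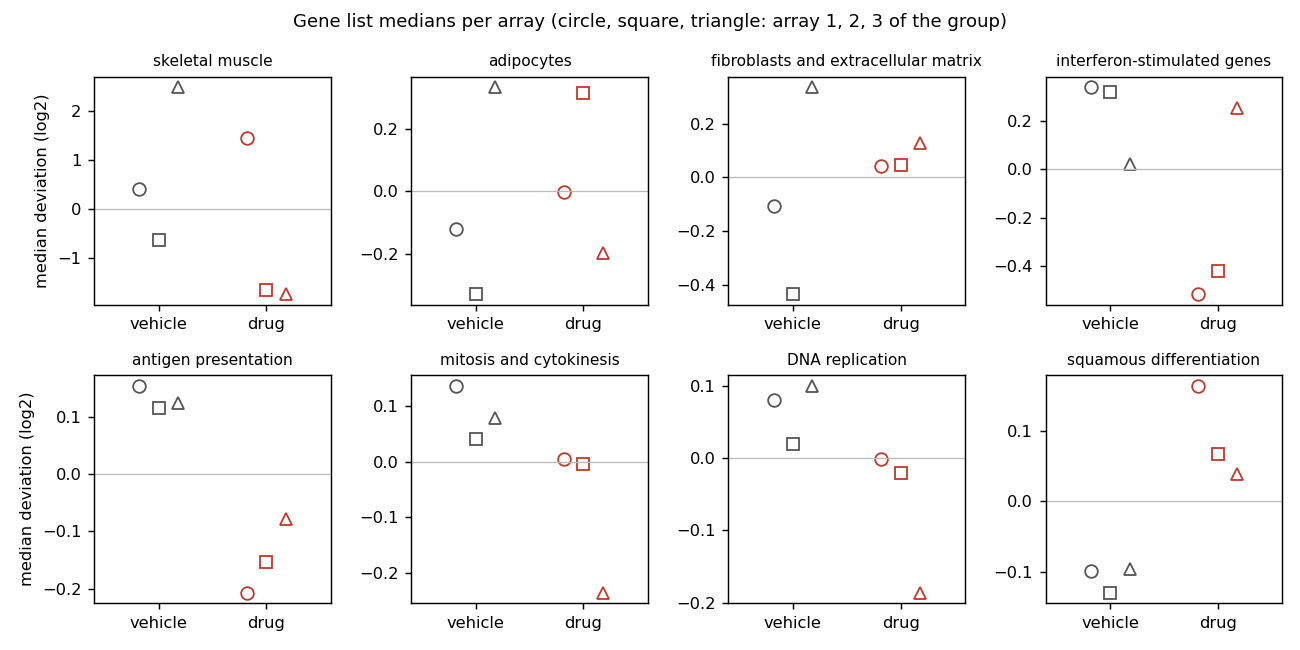
Median deviation of 8 gene lists in each array from the mean of the 6 arrays, in log2 units, with 1 point per array and its own vertical scale in each panel. Skeletal muscle medians spanned -0.63 to 2.49 within vehicle, and antigen presentation medians were 0.12 to 0.15 in vehicle and -0.21 to -0.08 in drug-treated tumors.

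In all, 18 of 45 lists passed with camera at a preset correlation, 12 higher and 6 lower. With an estimated correlation 0 lists passed and 5 had an unadjusted p under 0.05, and with fry, which tests whether a list's genes move one way on balance, 0 passed and 7 had an unadjusted p under 0.05. In fry's mixed test, which counts changes in either direction, 13 lists passed. Among them were antigen presentation (fry mixed adjusted p = 0.0038) and the p53 and FOXO targets (0.00152 each), which camera did not call. The mixed test was not run on other splits of the arrays. The 9 other ways of splitting the 6 arrays into 3 and 3 gave 9 to 21 called lists, and 2 of them gave more than the real split.

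**Figure D4:**
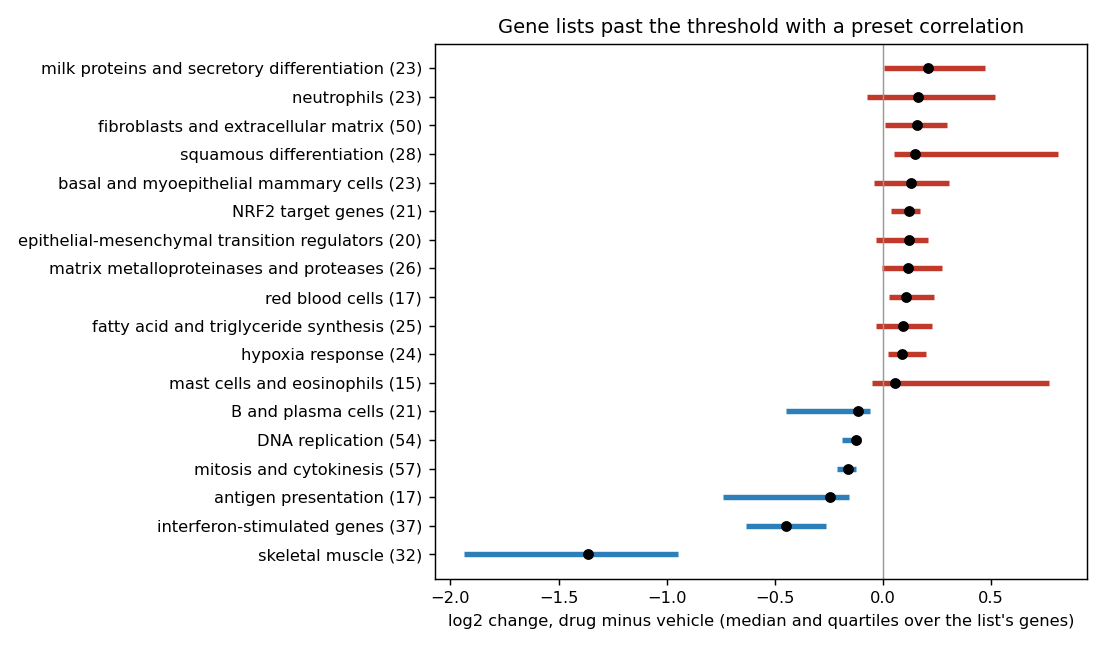
Median log2 change, drug minus vehicle, of the 18 gene lists past the threshold with camera at a preset correlation, as points, with lines from the lower to the upper quartile over each list's genes and the number of genes in brackets. The skeletal muscle median was -1.36 and the secretory median 0.21, and 0 of these lists passed with an estimated correlation.

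The other lists did not pass with camera. Dendritic cell genes had a median of -0.06 (adjusted p = 0.0703), and passed, as lower, with quantile normalization, with the adipocyte score as covariate, and without vehicle replicate 1 or 2, and nerve and Schwann cell genes of 0.05 (adjusted p = 0.0589). Of the signalling lists, IL6-STAT3 targets (0.501), FOXO targets (0.197), p53 targets (0.524), MAPK output (0.524), Wnt targets (0.797), ATF4 targets (0.883) and immediate early genes (0.67) had the adjusted p-values in brackets. Among their members Foxo1 and Irs2 differed by 0.27 ± 0.05 and 0.34 ± 0.07, and Perp and Cdkn1a, targets of p53, by 0.64 ± 0.11 and 0.39 ± 0.13 (SE, n = 3 per group). Other members were lower, with the FOXO target Bcl2l11 at -0.29 ± 0.08 and the p53 targets Tap1 and Pmaip1 at -0.26 ± 0.07 and -0.51 ± 0.19. Means were higher in 18 and lower in 16 FOXO targets, and higher in 20 and lower in 12 p53 targets. The metabolic lists of phosphatidylcholine and phosphatidylethanolamine synthesis (0.222), cholesterol synthesis (0.664), glycolysis (0.134), oxidative phosphorylation (0.67) and lysosome and autophagy (0.675) did not pass either. Nor did ER chaperones (0.138), nucleolar genes (0.195), ribosomal proteins (0.701) or apoptosis regulators (0.664). The cell type lists of endothelial cells (0.797), pericytes (0.797), adipocytes (0.501) and keratinocytes and hair follicle (0.892) also stayed above the threshold. The list median, mean and camera direction differed in sign for glycolysis, apoptosis, cholesterol synthesis, immediate early, lysosome, luminal, endothelial, pericyte, ATF4 and keratinocyte genes.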

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

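No paired analysis was possible because the labels give no replicate numbers. The alternatives without the muscle-rich arrays, with a muscle or adipocyte score as covariate, or without muscle genes in the background were chosen after the data were seen. With limma, 0 genes passed (1275 at an unadjusted p under 0.05) in the main test and in each other setting at that threshold, except without drug replicate 2, where 3 genes passed, of which Slc2a9 was 1 of the genes ranked over all genes and Gsta3 was named as a list member; over the settings that left out 1 array the counts ran from 0 to 3 for all genes and from 0 to 1 for the genes named by rank over all genes. At an unadjusted p under 0.01 with a fold of at least 2, 24 genes passed. The smallest adjusted p ranged from 0.0383 to 0.468 over settings, and 0 drug target genes passed in any of them. The count of called lists was 18, 0 with an estimated correlation and 0 with fry's one-way test. It was between 13 (arrays shifted to the same median) and 20 in the others, and 13 to 20 when 1 array was left out. Mitosis, DNA replication, interferon, antigen presentation, NRF2, squamous, basal, secretory and red blood cell lists kept their calls in all 6 of those. Of the lists, endothelial cells turned from -0.025 to 0.058, past the threshold, with the muscle-rich arrays left out, and fibroblasts from 0.16 to -0.06 without vehicle replicate 2, in a range of -0.06 to 0.362 when 1 array was left out; the cause was not tested. The median also changed sign, with camera's direction kept, for mast cells (0.056 to -0.003 without vehicle replicate 1) and B and plasma cells (-0.114 to 0.004 under the level filter), which lost their calls, and for immediate early genes (-0.007 to 0.032 without drug replicate 1), which gained one. Skeletal muscle shrank from -1.36 to -0.014 with the muscle score as covariate, where camera's direction changed, by construction, since that score is made from the same genes. Of 853 list settings, 75 kept camera's direction but not their call and 29 kept it and gained a call, the gains being in the T and NK cell, chemokine, macrophage, dendritic, drug target, nerve, ER chaperone, FOXO, glycolysis, adipocyte, endothelial and immediate early lists, and 47 changed direction, 44 of these in lists past the threshold in neither setting. Of 2818 gene settings over 189 genes, 8 changed sign. A pseudocount of 16 was not run because the values were already log2. Signal over background could not be assessed without detection calls.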

Other observations

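Orm1, Lyve1, Cd86, Fcgr1, Aif1 and Ly86 were named by the rule as list members, and the other genes in this paragraph were chosen after their values were seen. Igkv8-30, an immunoglobulin kappa variable segment, had the smallest unadjusted p of all genes, with a log2 difference of -1.94 ± 0.19 (SE, n = 3 per group, limma adjusted p = 0.231). Orm1, an acute phase protein, differed by 1.23 ± 0.23 and was the 1 adipocyte list member past limma's threshold when adjusted over the list alone. Igfbp2, an insulin-like growth factor binding protein, differed by -0.58 ± 0.10. Among macrophage genes, Cd86, Fcgr1, Aif1 and Ly86 were lower by means of -0.29, -0.48, -0.68 and -0.65, while Vsig4, Lyve1, F13a1 and Cd163 were higher by 1.43, 1.56, 0.98 and 0.61. Lyve1, also a member of the endothelial list, had an SE of 0.65 (n = 3 per group) and overlapping groups.

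The tests of macrophages, dendritic cells and interferon against MHC class II, both tests of skeletal muscle and the test of 1 tumor against mitosis were chosen only after the result was seen. The 95% intervals over arrays, and the bound that an interval wholly below 0 with over 50% of a change kept under a covariate argues against a whole cause, were added after the first values were seen. With 10 splits of the 6 arrays no share under 0.05 can be reached. The count of genes past limma's adjusted p was 0 in the real split and at most 0 in the others, as many in 10 of the 10 splits. The count at an unadjusted p under 0.05 was 1275 in the real split and at most 810 in the others, as many in 1 split. The count of called lists was 18 in the real split and at most 21 in the others, as many in 3 splits.

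A hypothesis of more macrophages of the Lyve1-positive tissue-resident kind, drawn from Lyve1, Vsig4, Cd163 and F13a1, was tested on 11 other markers, of which Ccl8 and Clec10a were also in lists tested before. It was not borne out: their median log2 change was -0.024, with 5 higher and 6 lower, and that of the 9 in no tested list was 0.02. Camera's p-value for this set of genes was 0.965. The median of the 4 genes seen first was 1.20. It lay above the 95% interval over arrays of the other markers' change, -0.46 to 0.62, or -0.30 to 0.47 for those in no tested list. Those 4 genes were chosen after their values were seen, and the intervals leave a smaller rise open. Fcna alone among the held-out markers differed by over 0.5, at 0.77.

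MHC class II genes were lower in drug-treated tumors in all 7 measured members, with a group difference of the array medians of -0.77 (95% interval -1.16 to -0.38, exact permutation p = 0.1, the smallest that 3 against 3 allows). Fewer macrophages of all kinds as the whole cause is argued against by the macrophage list, with 35 of 39 genes above the level filter. Its difference was -0.089 (95% interval -0.44 to 0.26). Its members did not move alike, with 15 higher and 24 lower, so a fall in only some macrophages stays open. The dendritic list differed by -0.077 (-0.30 to 0.14), but 10 of its 17 genes lay below that filter, so fewer dendritic cells stay open. A differing share of skeletal muscle is argued against as the whole cause. With the muscle score as covariate the class II difference was -0.70 (-1.22 to -0.19). With both muscle-rich arrays left out the class II difference was -0.68, but that interval, -1.54 to 0.18, spans 0. Leaving out these arrays cannot decide on a share of muscle, since the muscle genes' median change was then still -1.64. A lower interferon response is argued against as the whole cause only as scored by its list's median. With that score as covariate the class II difference was -0.91 (-1.46 to -0.36). The score is 1 median over 37 genes, so a fall in part of the response stays open. The muscle score moved the B and plasma cell difference from -0.15 to -0.05. The interferon score moved it to -0.30, away from 0, and the antigen presentation difference from -0.28 to -0.22. Neither covariate interval excludes a loss of over 50% of the difference, so each may contribute, and the treatment and chance stay open. The B and plasma cell list also fell, and fewer cells of that kind were not tested as a cause.

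Skeletal muscle genes differed by -1.40 between the array medians of the groups (95% interval -5.28 to 2.47, exact permutation p = 0.4). Their range over the vehicle arrays alone was 3.12, larger than the difference between groups. Muscle tissue taken with some samples regardless of group is a candidate explanation, and it was found from these same values. A treatment that lowers muscle genes in every tumor cannot be told apart from it with 3 arrays per group, since the interval spans 0.

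Mitosis genes differed by -0.16 between the array medians (95% interval -0.39 to 0.07, exact permutation p = 0.1, the smallest that 3 against 3 allows). Without drug replicate 3 the difference was -0.086 (-0.20 to 0.03), about as much as the 50% bound, so 1 tumor may carry much of the list's change. With the muscle score as covariate it was -0.13 (-0.44 to 0.18). With both muscle-rich arrays left out it was -0.21 (-0.74 to 0.33). That setting cannot decide on a share of muscle, since the muscle genes' median change there was still -1.64. Muscle genes were lower on average in the drug-treated arrays, with medians of 1.45, -1.66 and -1.74 against 0.40, -0.63 and 2.49 in vehicle. A smaller share of muscle would dilute tumor transcripts less and so raise mitosis genes, not lower them. That direction argues against dilution by muscle in these arrays, although the covariate moved the difference slightly towards 0. Whether the treatment or that tumor gave the lower values cannot be told apart with these arrays.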
